A study of Arabidopsis thaliana with 12 samples.

How the data were processed

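Total RNA from detached rosette leaves (leaf positions 3 and 4) of 3-week-old Arabidopsis thaliana plants was measured on 12 one-colour Agilent arrays, with Cy3-labelled cRNA, per the labels' protocols. Plants had grown in a cycle of 16 h of white light at 100 μmol m-2 s-1 and 8 h of darkness at 22 °C. Leaves were sampled before treatment (day 0) and after 4 days of continuous far-red light (730 nm, 1 μmol m-2 s-1), in wild-type Col-0 and in the mutants phyA-211 and phyB-9, which gives 6 groups. Each group held 2 arrays, which the series' design text calls biological duplicates. RNA with an integrity number of at least 7 was used, per the labels.

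Each array's deposited table held the scanner's spot intensity on a linear scale, extracted with Agilent Feature Extraction 11.5.1.1 and protocol GE1_1105_Oct12, per the file headers. The array design number was 031025. The processed signal in these tables is background-corrected, and the deposited tables also held quality columns for saturated spots, spots of uneven or outlying brightness, and spots well above background. The deposited value table held log2 values, and it matched the quantile-normalised log2 median spot signals without background subtraction to within 0.055 on every spot. Each of its columns correlated with the array's own log2 median signal at r of at least 0.999, and the column medians lay between 6.97 and 6.98. Its direction and log base were settled by that match, and what else was done to make it is not given in the sources used here.

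The main values were log2 of the processed signal minus each array's 75th percentile, over 61657 spots that are not controls. Spots flagged as uneven or outlying were left out, and the spots of one probe were averaged. Of 43603 probes, 18054 had 2 spots. A probe was tested if it was well above background on both arrays of at least 1 group and had a value on every array, which left 30702 probes. Another 12891 probes were not well above background in any group, and 10 were left out because of flagged spots. No spot was saturated.

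The number of arrays limits the precision, and signal over background limits how small a level can be read. The 75th percentile of the signal lay between 642 and 993 intensity units per array, and between 62.9% and 67.3% of probes were well above background. Where a probe was not well above background on any array of a group, its level there is only bounded. The fold is then given as at least the ratio of the brighter group's mean to the dimmer group's mean, after each dim value was raised to the lowest signal among probes well above background on its array.

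The 6 group means were fitted in one model with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 6 residual degrees of freedom and 2.17 prior degrees of freedom. The 12 comparisons were the 3 far-red responses (day 4 minus day 0), the 3 genotype differences at each day and the 3 differences between far-red responses. A probe was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison, and every adjusted p in the text comes from this limma fit. An exact test of 2 arrays against 2 cannot give a p below 0.333, so no comparison of a single value between 2 groups was tested that way. Simulated data took the real probes' means and the spreads that limma estimated, with 200 probes changed and noise independent between probes. In 1 draw for phyA-211 against Col-0 at day 0, the fit found 93.9% of probes changed by 4 on the log2 scale. It found 77.6% of those changed by 2 and 13.4% of those changed by 1, over 30702 probes. For the difference between the responses of phyB-9 and phyA-211 these shares were 90.9%, 59.7% and 1.49%. The shares hold where 200 probes change and vary independently, and the adjusted threshold is less strict where more do. Replicates in the data moved together across probes, as given below, which the simulation left out. In the data that comparison called 5009 probes, with differences as small as 0.55, so its own share of missed probes is not given by the simulation.

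All day 0 arrays lay on slide 1 (scan 1) and all day 4 arrays on slide 2 (scan 2), per the file headers. Day and slide cannot be told apart in the far-red responses. Genotype differences at one day lie within one slide, and a slide effect that adds the same amount to all genotypes cancels in the differences between responses. On each slide both Col-0 arrays lay in row 1 and both phyB-9 arrays in row 2, with 1 phyA-211 array in each row.

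The files give probe IDs only. None of these IDs matched the reference table of genes (0 probes), and the files do not pair IDs with genes. The choices made before the data were examined that need gene names were therefore not carried out: a single probe per locus, 23 gene lists, and the transcripts of PHYA and PHYB, the genes mutated in the 2 mutant lines. The unit tested is the probe. The rule for named items, also fixed before the data were examined, took the largest rises and falls among called probes that were well above background on both arrays of both groups and whose arrays did not overlap, and ranked probes detected in 1 group and not in the other apart, by the bound of their fold. For a difference between responses, the rule asked for signal well above background on both arrays of at least 1 group. Its clause on gene symbols could not be applied, and at most 2 probes that rose and 2 that fell are given for a comparison.

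The size of the far-red response was compared between 2 genotypes over the probes called in the remaining genotype, with no p-value. A response score per array was added after the data were seen. It is 0.5 times the difference between the mean change of the probes that were at least 1 higher (log2) at day 4 than at day 0 over all arrays and the mean change of those at least 1 lower, each relative to the day 0 mean, so that a factor common to an array cancels. Its order over the genotypes was also read from the data, so it was tested by exact permutation over 90 arrangements of the 6 day 4 arrays with any of the 6 orders of the genotypes allowed. A two-sided test of the 1 order seen was used only to compare the alternatives.

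Alternatives were normexp background correction of the median spot signal (offset 50; the mean spot signal planned for it was not among the deposited columns), quantile normalisation, no filter on dim probes, a filter to the 24063 probes well above background on all 12 arrays, the replicate number as a block, eBayes with trend and robust options, a minimum change of 2-fold, the deposited value table, leaving out each array, and fits of only the arrays compared or only those of one day. Scaling to 8 spike-in control probes, centring on the median of tested probes and other replicate blocks were added after the data were seen. Leaving out an array changes the spread shared by all 6 groups and its degrees of freedom, also for comparisons that the array does not enter.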

Results

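The transcriptomes of detached Arabidopsis leaves were measured before and after 4 days of continuous far-red light in wild-type Col-0 and in mutants of 2 red and far-red light receptors, phytochrome A (phyA-211) and phytochrome B (phyB-9). Each of the 6 groups had 2 arrays. Arrays of one group correlated at r between 0.979 and 0.99 across the 30702 tested probes, arrays of different genotypes at r between 0.972 and 0.988 at day 0 and between 0.915 and 0.985 at day 4, and arrays of different days at r between 0.619 and 0.793. The series title asks whether the 2 phytochromes act against each other in leaf senescence under far-red light. The files do not pair probes with genes, so single items are given by probe ID.

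The first question was what changed in the leaves of each genotype over 4 days of far-red light. In Col-0, 10808 probes rose and 10175 fell from day 0 to day 4, which is 68.3% of those tested, and 3394 rose and 4694 fell at least 4-fold. In phyA-211, 11455 rose and 11379 fell (74.4%), of which 4167 and 5753 changed at least 4-fold. In phyB-9, 10503 rose and 8988 fell (63.5%), of which 2851 and 4098 changed at least 4-fold. Among the risers in Col-0, A_84_P16138 rose by 10.77 ± 0.54 on the log2 scale (SE, n = 2 arrays per day, adjusted p = 2.2e-06) and A_84_P857167 by 10.10 ± 0.58 (adjusted p = 3.8e-06). A_84_P23852 fell by 10.73 ± 0.39 (adjusted p = 6.9e-07) and A_84_P812905 fell by 10.73 ± 0.95 (adjusted p = 2.8e-05). Day 4 arrays were all on another slide than day 0 arrays, so day and slide cannot be told apart here. No day 4 group was kept in white light or in darkness. The change named the far-red response therefore also holds the loss of white light and of the light and dark cycle, and the 4 days passed. The share of called probes that were higher moved from 53.9% to 66.4% in phyB-9 when arrays were scaled to spike-in controls, which raised the median change of all probes from 0.13 to 0.50 in phyB-9 against 0.01 in Col-0 and 0.0016 in phyA-211. Centring on the median of tested probes put these median changes at 0.18, 0.17 and 0.20.

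The 3 genotypes shared most of this response. The same 8240 probes (26.8%) rose in all 3 genotypes and the same 7827 (25.5%) fell in all 3, while 4630 were called in none and 186 were called in opposite directions in different genotypes. Of the probes that rose in Col-0, 9699 also rose in phyA-211 and 9022 in phyB-9, where independent lists would share 4032 and 3697. Of those that fell in Col-0, 9374 also fell in phyA-211 and 8311 in phyB-9, where independent lists would share 3771 and 2979. These comparisons have no arrays in common, but each sets the same slide against the same other slide. A slide or hybridisation effect particular to each probe would recur in every genotype. Independent lists are therefore no reference for the absence of a shared far-red response, and the overlaps cannot tell such an effect from it. Among the 100 probes with the brightest mean signal over all arrays, 37 rose and 40 fell in Col-0, 44 rose and 36 fell in phyA-211, and 27 rose and 50 fell in phyB-9.

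Many probes crossed the detection limit between the days, which lay on different slides. In Col-0, 1094 probes were well above background on both day 0 arrays and on neither day 4 array, and 1537 on both day 4 arrays and on neither day 0 array. The corresponding numbers were 1830 and 1348 in phyA-211 and 967 and 1397 in phyB-9. In all 3 genotypes alike, 606 probes were detected only at day 0 and 721 only at day 4. Losses seen in 1 genotype numbered 796 in phyA-211, 133 in Col-0 and 126 in phyB-9, and gains seen in 1 genotype numbered 227 in phyA-211, 293 in Col-0 and 379 in phyB-9. Whether these numbers differ between genotypes was not tested. The detection limit itself moved between the slides. From day 0 to day 4 its group mean went from -5.89 to -6.29 in Col-0, -5.72 to -6.08 in phyB-9 and -6.02 to -5.98 in phyA-211. With a bounded change of at least 2-fold, losses and gains numbered 1034 and 974 in Col-0, 1551 and 1119 in phyA-211, and 910 and 880 in phyB-9. The excess of gains in Col-0 and phyB-9 was then gone.

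The next question was whether the response differed in size between genotypes. Over the 10808 probes that rose in Col-0, the median rise was 1.48 ± 0.10 on the log2 scale in phyA-211 (SD of the 2 day 4 arrays, n = 2) and 1.09 ± 0.08 in phyB-9. Over the 10175 probes that fell in Col-0, the median change was -2.17 ± 0.13 in phyA-211 and -1.59 ± 0.14 in phyB-9. The gaps of -0.39 and 0.58 exceeded the combined SD of the arrays (0.12 and 0.19), but scaling to spike-in controls put the first at -0.11, within that SD, and the second was 0.19 with normexp correction, 0.31 with the deposited values and 1.00 with spike-in scaling. The Col-0 medians lay between those of the mutants: over probes called in phyA-211, its median changes were 1.23 ± 0.15 and -1.55 ± 0.25 against 1.01 ± 0.09 and -1.32 ± 0.13 in phyB-9, and over probes called in phyB-9 they were 1.27 ± 0.09 and -2.0 ± 0.22 against 1.38 ± 0.07 and -2.32 ± 0.12 in phyA-211. Of these 4 gaps to Col-0, 2 were within the combined SD of the arrays: that over the fallers of phyA-211 (0.23 against 0.28) and that over the risers of phyB-9 (0.11 against 0.12). The other 2, -0.22 and -0.32, also came within their SDs of 0.17 and 0.25 when 1 Col-0 array of day 4 was left out. Without replicate 2 the gaps of phyB-9 to Col-0 were -0.11 and 0.05, and without replicate 1 those of phyA-211 to Col-0 were 0.05 and -0.18. Scaling to spike-in controls turned the gap between phyB-9 and Col-0 over the risers of phyA-211 from -0.22 to 0.17, and kept the direction of the others. It put the gap over the fallers of phyA-211 at 0.66, beyond the SD of 0.28. With normexp correction the gap of -0.32 over the fallers of phyB-9 was -0.061.

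**Figure D1:**
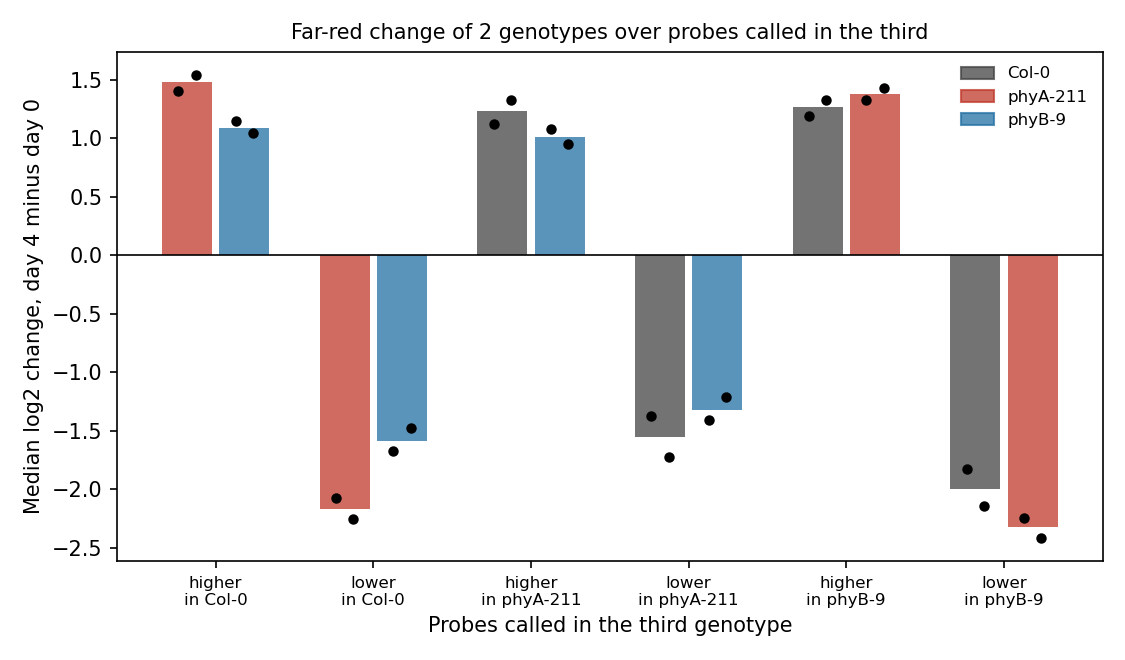
Median log2 change from day 0 to day 4 (y axis) in 2 genotypes over the probes called higher or lower in the third (x axis); bars are medians over probes of the group mean change, and points are the 2 day 4 arrays against the mean day 0 level. The phyA-211 bars are longer than those of phyB-9 over the probes called in Col-0, 1.48 against 1.09 for risers and -2.17 against -1.59 for fallers; with spike-in scaling the comparison of phyB-9 with Col-0 over the risers of phyA-211 turns round.

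Of the 8240 probes that rose in all 3 genotypes, 50.2% rose most in phyA-211, less in Col-0 and least in phyB-9, and of the 7827 that fell, 51.4% fell in that order. Probes of one array vary together, and the day 4 replicates themselves differed along this response, so these shares add nothing to the order of the arrays. The response score, a measure chosen after the data were seen that uses 7369 rising and 8157 falling probes, was 2.31 ± 0.16 in phyB-9 (SD, n = 2), 2.60 ± 0.24 in Col-0 and 3.05 ± 0.09 in phyA-211 at day 4, and within 0.02 of 0 in each genotype at day 0. All 12 pairs of day 4 arrays from different genotypes stood in the order phyB-9, Col-0, phyA-211. This order was read from the same arrays, and a test that allows any of the 6 orders of the genotypes gave p = 0.067 (exact permutation, the smallest p that it can give), so the order is described here and not shown to be beyond chance. The lower Col-0 array scored 2.43 and the higher phyB-9 array 2.42, and this pair changed places with quantile normalisation, with the deposited value table and over the 24063 probes above background on all arrays.

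**Figure D2:**
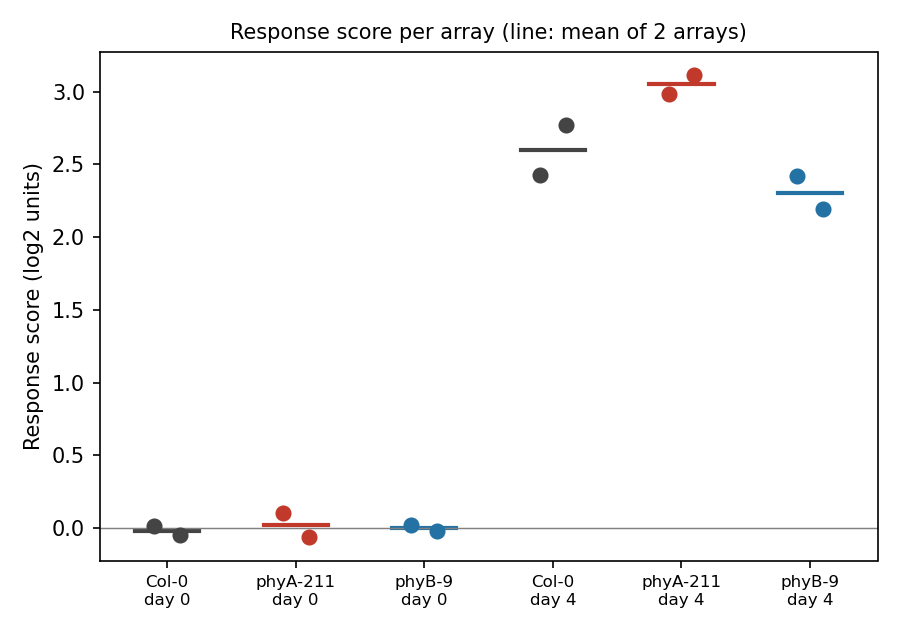
Response score (y axis, log2 units) of each of the 12 arrays by genotype and day (x axis); points are arrays and lines the mean of 2 arrays. The day 0 arrays lie near 0, and the day 4 means are 2.31 in phyB-9, 2.60 in Col-0 and 3.05 in phyA-211.

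Before treatment, phyA-211 leaves differed from Col-0 in 17 of 30702 probes, 10 higher and 7 lower. A_84_P17061 was well above background on all 8 arrays of Col-0 and phyB-9 and on none of the 4 arrays of phyA-211. It was at least 147-fold lower in phyA-211 than in Col-0 at day 0 (adjusted p = 2.2e-07) and at least 503-fold lower at day 4 (adjusted p = 3.4e-08). A_84_P22244 showed the opposite pattern, well above background on the 4 phyA-211 arrays and on none of the other 8, and at least 87.2-fold higher than in Col-0 at day 0 (adjusted p = 0.00037). Of the 17 probes, 9 of the 10 higher and 5 of the 7 lower were called in the same direction at day 4, and these 14 also set phyA-211 apart from phyB-9 at both days. Fits of only the 4 arrays compared called 1 probe at day 0, and of only the 6 day 0 arrays 2. Normexp correction gave 28, the deposited values gave 32, and no filter on dim probes gave 10. The count at day 0 fell to 3 without phyA-211 replicate 1 of day 0, to 8 without either Col-0 array of day 0, to 9 without either phyA-211 array of day 4 and to 7 without either phyB-9 array of day 4. Other scalings moved the share of calls that were higher from 58.8% to between 54.2% and 69.6%.

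After 4 days of far-red light more probes set phyA-211 apart from Col-0, with 733 higher and 2003 lower in phyA-211. These differences ran along the far-red response. Of the 2003 lower probes, 1357 (67.7%) were among those that fell in phyB-9, where independent lists would share 586. Of the 733 higher probes, 403 (55.0%) were among those that rose in phyB-9, where 251 would be shared. The phyB-9 arrays enter neither side of the genotype comparison. Day 4 replicates of 1 genotype also differed along this response, so independent lists do not give what the absence of a genotype effect would. A_84_P604401 was 39.0-fold higher in phyA-211 at day 4 (log2 5.29 ± 0.39, SE, n = 2 per group, adjusted p = 0.0015), close to its 30.3-fold difference at day 0. Fits of only the 4 arrays compared called 3 probes, and of only the 6 day 4 arrays 641. Spike-in scaling gave 1104 and no filter on dim probes 1660. The total of 2736 rested on single arrays: it was 296 without Col-0 replicate 1, 4703 without Col-0 replicate 2, 1133 and 506 without phyA-211 replicates 1 and 2, and 1634 without either phyB-9 array of day 4, and 1775 and 1700 without a day 0 array of Col-0 and phyB-9. The phyB-9 and day 0 arrays do not enter this difference. Without one of them only the spread shared by all groups and its degrees of freedom changed, not the differences themselves. The share of calls that were higher was 26.8%, and between 24.1% and 46.4% with other scalings.

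In phyB-9, 33 probes were higher and 17 lower than in Col-0 at day 0, and 134 were higher and 148 lower at day 4. A_84_P500750 was 9.70-fold higher at day 0 (log2 3.28 ± 0.19, SE, n = 2 per group, adjusted p = 0.0026), and A_84_P765883 was 6.52-fold lower (log2 -2.71 ± 0.18, adjusted p = 0.0026). At day 4, A_84_P762010 was 170-fold lower in phyB-9 (log2 -7.41 ± 0.76, adjusted p = 0.0059), and this call was lost without Col-0 replicate 2 (adjusted p = 0.050) or phyB-9 replicate 2 (adjusted p = 0.055), within a range of 0.0010 to 0.055 over its 20 alternatives. Of the 50 probes called at day 0, 12 of the higher and 9 of the lower were called in the same direction at day 4. A set of 15 probes marked phyB-9 off from both other genotypes at both days, 7 above and 8 below. A_84_P762010 was among these 8, so its difference was present before treatment. At day 0 it stood at -6.10 in phyB-9, with 1 of 2 arrays well above background, against 1.53 in Col-0. Of the 148 probes that were lower at day 4, 123 (83.1%) were among those that rose in phyA-211, where independent lists would share 55.2. Of the 134 higher probes, 48 were among those that fell in phyA-211, where 49.7 would be shared, which is no excess. The 2 lists were not compared by a test. Since day 4 replicates differed along the response, independent lists are no reference for the absence of a genotype effect here either.

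The phyB-9 counts also depended on which arrays were fitted, through the spread shared by all groups as well as through the arrays compared. Fits of only the 4 arrays compared at day 4 called 0 probes by limma (4841 at an unadjusted p under 0.05), and of only the 6 day 4 arrays 25. Over the probes above background on all arrays, 43 were called. At day 0 such fits called 0 probes by limma from the 4 arrays (1576 at an unadjusted p under 0.05) and 0 from the 6 arrays (1579). Spike-in scaling, the filter to all arrays and no filter gave 24, 28 and 31. Deviations of same-numbered arrays correlated at 0.34 to 0.62 within day 0. A replicate block within each day also lowered the day 0 count, as given with the processing below. At day 4 the count of 282 became 644 without Col-0 replicate 1, 76 without Col-0 replicate 2, 138 and 58 without phyB-9 replicates 1 and 2, and 168 without either phyB-9 array of day 0. At day 0 the count of 50 fell to between 8 and 29 without any one array other than phyB-9 replicate 1 of day 0, with 12 and 16 without Col-0 replicates 1 and 2, 23 without phyB-9 replicate 2, 29 without either phyA-211 array of that day, and 27, 21 and 8 without a day 4 array of Col-0, phyA-211 and phyB-9. Other scalings gave between 33.3% and 71.4% higher at day 0 against 66.0%, and between 37.1% and 55.5% at day 4 against 47.5%.

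The 2 mutants were set against each other directly, since the series title names opposite action. At day 0, 61 probes were higher and 45 lower in phyB-9 than in phyA-211, and at day 4 the numbers were 7265 and 5357, or 41.1% of the tested probes. A_84_P15319, at 7.93 to 8.02 on the log2 scale in the 3 genotypes at day 0, was 63.6-fold higher in phyB-9 than in phyA-211 at day 4 (log2 5.99 ± 0.78, SE, n = 2 per group, adjusted p = 0.0020). A_84_P146039 was 119-fold lower in phyB-9 (log2 -6.89 ± 0.51, adjusted p = 0.00035), and it was not well above background on any day 0 array. Of the 7265 probes higher in phyB-9, 4584 (63.1%) were among those that fell in Col-0 and 741 among those that rose, where independent lists would share 2408 and 2557. Of the 5357 lower probes, 3853 (71.9%) were among those that rose in Col-0 and 442 among those that fell, where 1886 and 1775 would be shared. Day 4 replicates of 1 genotype differed along the far-red response too, so independent lists are not the reference for the absence of a genotype effect. The day 4 count was 5361 without phyA-211 replicate 2 and 3742 without phyB-9 replicate 2 of day 4, and the day 0 count of 106 was 37 without phyA-211 replicate 1, 62 and 52 without phyB-9 replicates 1 and 2, and 50 without either phyB-9 array of day 4. Fits of only the 4 arrays compared called 1 probe at day 0, and of only the 6 day 0 arrays 6. Over the probes above background on all arrays, 58 were called. The share of calls that were higher was 57.6% at day 4 and between 46.0% and 72.2% with other scalings, and 57.5% at day 0 and between 40.7% and 70.9%.

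**Figure D3:**
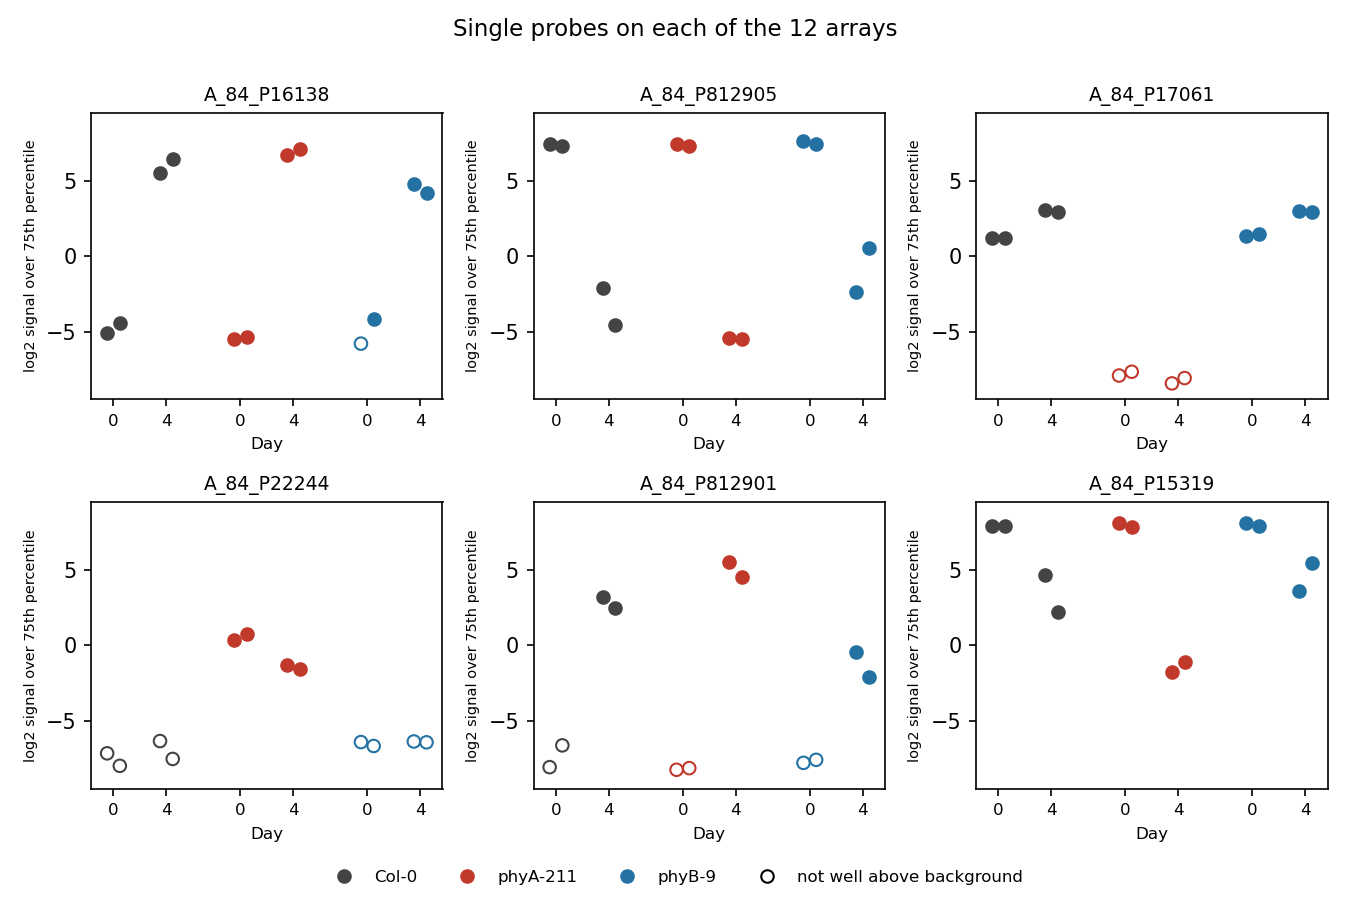
Log2 signal over the array's 75th percentile (y axis) of 6 probes on each of the 12 arrays by genotype and day (x axis); open points were not well above background. A_84_P17061 is dim on the 4 phyA-211 arrays and A_84_P22244 bright on them alone, and at day 4 A_84_P812901 is higher and A_84_P15319 lower in phyA-211 than in phyB-9.

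The differences of the 2 mutants from Col-0 were set against each other across probes. Their correlation across probes, which are not independent replicates, was 0.41 at day 0 and -0.32 at day 4. The day 4 value was -0.13 without the filter on dim probes and -0.48 over probes above background on all arrays. If probes varied independently, groups without any difference would give 0.50, because both share the Col-0 arrays. The covariance was 0.068 at day 0 and -0.15 at day 4, against 0.076 from the shared arrays alone on that assumption. Day 4 replicates instead differed along the far-red response (r = 0.47 in Col-0, -0.42 in phyB-9 and 0.17 in phyA-211). The values without any difference at day 4 could therefore lie far from 0.50 and 0.076. At day 4, 46 probes were above Col-0 in phyA-211 and below it in phyB-9, where independent lists would share 3.53, and 15 were below it in phyA-211 and above it in phyB-9, where 8.74 would be shared. In the same direction, 13 were above and 15 below Col-0 in both, where independent lists would share 3.20 and 9.66. All 4 overlaps use lists that share the Col-0 arrays, and how many shared calls these arrays alone would give at these list sizes was not measured. With only 2 Col-0 arrays the shared controls could not be split into 2 sets of 2 arrays. With 1 Col-0 array for each mutant, the day 4 correlation was -0.58 one way round and -0.04 the other, so that its size depended on which Col-0 array served which mutant, and the day 0 correlations were -0.05 and -0.11. Without Col-0 replicates 1 and 2 of day 4 the day 4 correlation was -0.20 and -0.11, and without phyB-9 replicate 2 it was -0.19. The day 0 correlation was 0.66 without Col-0 replicate 2 and 0.22 without phyA-211 replicate 2 of that day. If probes varied independently, groups without any difference would give 0.67 with 1 Col-0 array left and 0.41 with 1 mutant array left.

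Whether the far-red response itself differed was tested by the difference between responses. It differed between phyB-9 and phyA-211 in 5009 probes, 2801 above and 2208 below 0. Of the 2801, 1853 were among the probes that fell in Col-0, a smaller fall or a rise in phyB-9. Of the 2208, 1684 were among those that rose in Col-0. Independent lists would share 928 and 777. The limit on independent lists holds here as well, since the day 4 arrays enter this difference. Against Col-0, the response differed in 126 probes in phyA-211 (37 above, 89 below 0) and in 15 probes in phyB-9 (1 above, 14 below 0). The 1 probe above 0 in phyB-9 was A_84_P22425, which fell from -1.65 to -8.33 in Col-0 and from -1.23 to -5.61 in phyB-9 and was not well above background in Col-0 at day 4, so that its difference in response was only 0.26 with dim arrays set to the detection limit. The 3 counts rested on single arrays: they were 852 without Col-0 replicate 2 of day 4 for phyA-211, 48 without Col-0 replicate 1 of day 4 for phyB-9, and 248 without phyB-9 replicate 2 of day 4 for the 2 mutants. Without either Col-0 array of day 0 no probe was called by limma in the comparisons with Col-0, where 4690 and 4982 probes for phyA-211 and 2403 and 2965 for phyB-9 had an unadjusted p under 0.05. For phyB-9 against Col-0, limma called 0 probes with normexp correction (3329 at an unadjusted p under 0.05), with the deposited value table (3317), over the probes above background on all arrays (2399) and with trend and robust options (3050). For phyA-211 against Col-0, spike-in scaling, no filter, the value table and normexp gave 25, 37, 209 and 281. The replicate number as a block gave 42, and a block within each day lowered the count further. Between the mutants, no filter and spike-in scaling gave 2433 and 3134. The share of calls above 0 was 29.4% for phyA-211 and 23.8% to 40.0% with other scalings, 6.67% and 0% to 41.7% for phyB-9, and 55.9% and 42.8% to 76.2% between the mutants.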

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

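The tests of a slide shift, of the scaling and of the slide's rows were chosen after the results were seen, and those of signal compression and of wrong labels before.

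The far-red response differed between genotypes by the test of the difference itself in 126 probes for phyA-211 against Col-0, in 15 for phyB-9 against Col-0 and in 5009 for phyB-9 against phyA-211. Leaving out an array also changes the spread shared by all groups, so a count can move without an array that does not enter its difference. The first count rested on single arrays: without Col-0 replicate 2 of day 4 it was 852, without phyA-211 replicate 2 of day 0 it was 4, without any other day 0 array it was 0 by limma (4690 to 5521 probes at an unadjusted p under 0.05, against 5701 with all arrays), and without the remaining day 4 arrays it was 27 (Col-0 replicate 1), 14 and 5 (phyA-211 replicates 1 and 2) and 23 (either phyB-9 array). The second was 48 and 1 without Col-0 replicates 1 and 2 of day 4, 9 without phyB-9 replicate 2 of day 0, and 0 without any day 0 array of Col-0 or phyA-211 (2403 to 3129 at an unadjusted p under 0.05); limma also called 0 with normexp correction (3329), the deposited value table (3317), the filter to all 12 arrays (2399) and trend and robust options (3050). The third fell to 248 and 2130 without phyB-9 replicates 2 and 1 of day 4, to 556 and 3120 without phyA-211 replicates 2 and 1 of day 4, to 1251 and 2233 without phyA-211 replicates 1 and 2 of day 0, and to 1071 and 1028 without phyB-9 replicates 1 and 2 of day 0.

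Among these, A_84_P812901 was not well above background on any day 0 array and stood at 5.03 in phyA-211, 2.86 in Col-0 and -1.26 in phyB-9 at day 4 (log2 over the 75th percentile, n = 2 each). Its response differed by -6.79 ± 0.90 between phyB-9 and phyA-211 (SE, adjusted p = 0.010), or -6.59 with dim arrays set to the detection limit. A_84_P764402 had a difference of -7.48 ± 0.98 (adjusted p = 0.0099; -6.30 at the detection limit), being well above background in phyB-9 at both days and in the other genotypes only at day 4. A_84_P235073 had a difference of 10.07 ± 1.16 (adjusted p = 0.0067; 7.98 at the detection limit), with signal lost in phyA-211 and gained in phyB-9. A_84_P81249 had a difference of 9.34 ± 1.81 (adjusted p = 0.023; 6.22 at the detection limit), and this call was lost without either phyB-9 array of day 0 (adjusted p = 0.056 and 0.062), phyB-9 replicate 2 of day 4 (0.097) or phyA-211 replicate 2 of day 4 (0.056), within a range of 0.0098 to 0.097 over its 20 alternatives.

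One signal lay outside the probes compared. The 12 spots of the control ETG10_236652 were well above background on 0 of 6 day 0 arrays and on 6 of 6 day 4 arrays, with means of -6.31 ± 0.26 and -4.67 ± 0.53 (SD, n = 6), a difference of 1.64.

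Between 63.5% and 74.4% of tested probes differed between the days in each genotype, with each day on its own slide. A shift of slide 2 that acts on all spots of a given brightness is argued against by the 8 spike-in control probes, which span 8.74 to -3.83 in scaled log2 signal at day 0 and differed between the days by at most 0.27, against a median change of 1.55 among the called probes of Col-0. Single controls did move: of 16 others above background on all 12 arrays, 15 changed by at most 0.26, but DCP_20_7 rose by 0.81 from -3.96, and the dim DCP_20_9 rose by 2.18 (above background on 3 of 6 day 4 arrays). Scaling is argued against as the whole source, since at least 84.0% of the called probes of each genotype were also called under each of 5 other scalings. A slide or hybridisation effect particular to each probe cannot be told apart from the day, because 0 slides held arrays of both days. Far-red light, the loss of white light and of the light and dark cycle, the time since detachment and leaf age also stay open. No day 4 group was kept in white light or in darkness.

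At day 4 the response score was lowest in phyB-9 and highest in phyA-211, and the arrays were brighter in that order reversed, with 75th percentile signals of 993 and 913 in phyB-9, 939 and 856 in Col-0, and 843 and 772 in phyA-211 (the brighter array scored lower in 2 of the 3 genotypes). Compression of signals on brighter arrays is argued against by the spike-in probes, whose slope in phyB-9 was 0.992 times that in phyA-211, where the scores stood at a ratio of 0.756. A genotype label at day 4 that did not match day 0 is argued against by 125 probes called between genotypes at day 0. Over these, each of the 6 day 4 arrays matched its own genotype's day 0 arrays best. The correlation was at least 0.765 above that with any other genotype. Labels exchanged between genotypes at both days would pass this test. For the row of the slide, the phyA-211 array was to exceed both others of its row by more than the pooled SD between replicates (0.18). In row 2 it exceeded the phyB-9 arrays by at least 0.70, which argues against the row there, though on 1 phyA-211 array. In row 1 it exceeded the Col-0 arrays by at least 0.21. That gap between single arrays is little more than the SD, so it does not settle the point for phyA-211 over Col-0. For phyB-9 against Col-0 the row stays open, since 0 rows held both. The phyA-211 array of row 2 scored 0.13 above that of row 1, where phyB-9 (row 2) scored -0.29 relative to Col-0 (row 1). This runs against a row effect, but 0.13 rests on 1 array per row and is within the SD between replicates. A candidate explanation for phyA-211, as a hypothesis from the same data, is a faster or larger far-red response in that genotype. For phyA-211 over Col-0 the spread between single arrays stays open beside it, and for phyB-9 genotype and row stay open side by side.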

How the results depend on the processing

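Scaling to spike-in controls, centring on the median, the replicate blocks within a day or crossed, and the response score were chosen after the results were seen. Of 476 alternative values of 21 results, 349 stayed within their range or on their side of the threshold, 123 moved, 3 lost their significance and 1 reversed. For 17 named probe values, 340 of 346 alternatives kept the call, 6 lost it and 0 reversed. The cause of a change was not tested. Leaving out an array removes its values and also changes the spread shared by all groups and its degrees of freedom.

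The far-red responses kept their counts within 1.5 times under all alternatives, and without any one array they ranged from 17215 to 21045 in Col-0, from 20229 to 22846 in phyA-211 and from 15004 to 19584 in phyB-9. A group left with 1 array is assumed to vary like the others. Without any one array, phyA-211 against Col-0 ranged from 3 to 16 calls at day 0 and from 296 to 4703 at day 4, phyB-9 against Col-0 from 8 to 36 and from 58 to 644, and phyB-9 against phyA-211 from 37 to 109 and from 3742 to 12836. Differences of responses ranged from 0 to 852 (phyA-211 against Col-0), from 0 to 48 (phyB-9 against Col-0) and from 248 to 5700 (phyB-9 against phyA-211), with 4690 and 2403 or more probes at an unadjusted p under 0.05 where limma called 0. The correlation of the mutants' differences from Col-0 ranged from 0.22 to 0.66 at day 0 and from -0.40 to -0.11 at day 4. If probes varied independently, 0.41 and 0.67 would arise without any difference when 1 mutant or 1 Col-0 array is left.

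In the order phyA-211 against Col-0 at day 0, its response difference and the response difference of phyB-9 from Col-0, normexp correction gave 28, 281 and 0 calls (3329 at an unadjusted p under 0.05 by limma) and the deposited values gave 32, 209 and 0 (3317). Normexp put the phyB-9 minus phyA-211 change over probes lower in Col-0 at 0.19 and the phyA-211 minus Col-0 change over probes lower in phyB-9 at -0.061, the value table put the former at 0.31, and both put the day 4 correlation at -0.46. A test of the 1 order of the response score that was seen, which could only give its smallest p of 0.022 with the main values, had an exact permutation p of 0.067 with quantile normalisation, with the value table and with the filter to all 12 arrays.

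Without a filter on dim probes the counts were 10 and 31 for phyA-211 and phyB-9 against Col-0 at day 0, 1660 for phyA-211 at day 4, and 37, 6 and 2433 for the response differences of phyA-211 and phyB-9 from Col-0 and between the mutants, with a day 4 correlation of -0.13. The filter to all 12 arrays, which tests fewer probes, gave 28 for phyB-9 against Col-0 and 58 against phyA-211 at day 0, 43 against Col-0 at day 4, 0 for its response difference from Col-0 (2399 at an unadjusted p under 0.05 by limma) and a day 4 correlation of -0.48. Trend and robust options gave 0 for that response difference (3050), and centring gave 8. A minimum of 2-fold left 1799 probes for phyA-211 against Col-0 and 6939 for phyB-9 against phyA-211 at day 4.

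Spike-in scaling gave 24 for phyB-9 against Col-0 at day 0, 1104 for phyA-211 against Col-0 at day 4, and 25, 24 and 3134 for the response differences. It put the phyB-9 minus phyA-211 change at -0.11 over probes higher and 1.00 over probes lower in Col-0, and the phyB-9 minus Col-0 change at 0.17 over probes higher in phyA-211, a reversal, and 0.66 over probes lower.

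Fits of only the 4 arrays compared gave 1, 0 (1576 at an unadjusted p under 0.05 by limma) and 1 calls at day 0 for phyA-211 and phyB-9 against Col-0 and phyB-9 against phyA-211, and 3 and 0 (4841) at day 4 for the first 2 of these. Fits of only the 6 arrays of a day gave 2, 0 (1579) and 6 at day 0, and 641 and 25 at day 4. Both have fewer residual degrees of freedom.

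The labels give replicates of different groups no more than a shared number. Deviations of arrays with the same number correlated at 0.34 to 0.62 within day 0, at -0.52 to 0.29 within day 4 and at -0.05 to 0.07 across days. The number as a block gave 42 for the response difference of phyA-211 from Col-0. A block within each day gave 0 for it (7015 at an unadjusted p under 0.05 by limma), 7 for phyB-9 and 14 for phyB-9 against Col-0 at day 0. With the phyB-9 day 4 numbers crossed, the block gave 573 for phyB-9 against Col-0 and 14223 against phyA-211 at day 4.

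A mean over each gene's probes and camera tests of gene lists were not run, since the probes were not paired with genes. Signal over background limits the levels of probes lost or gained between days, which are only bounded.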

Other observations

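The test of a common scaling was chosen after the result was seen.

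Genotype marks that were present before treatment and stayed through it fell into small sets. Called above both other genotypes at both days were 9 probes in phyA-211 and 7 in phyB-9, and called below both were 5 in phyA-211 and 8 in phyB-9. For Col-0 this count was 0 in either direction. A mark of Col-0 needed a call against both mutants at day 0. Those lists were short, with 10 and 7 probes for phyA-211 and 33 and 17 for phyB-9. The 0 therefore does not show that no probe set Col-0 apart. A_84_P550153 stood above both mutants at both days, but at day 0 it was called only against phyB-9. At day 4 it was at 0.49 in Col-0, -1.51 in phyA-211 and -1.44 in phyB-9 (log2 over the 75th percentile, n = 2 each). By detection alone, 2 probes were well above background on all 4 phyA-211 arrays and on none of the other 8, and 3 on all 4 phyB-9 arrays and on none of the others. Missing from phyA-211 and present on all arrays of the others was 1 probe, and 1 was missing from phyB-9 in the same way. The latter, A_84_P580100, was dim in the other genotypes too. It was at least 4.76-fold lower in phyB-9 than in Col-0 at day 0 and was not called there (adjusted p = 0.37 by limma). The probe missing from phyA-211 rose in the genotypes that had it, from 1.18 ± 0.00 to 3.00 ± 0.12 in Col-0 and from 1.41 ± 0.05 to 2.98 ± 0.03 in phyB-9 (log2 over the 75th percentile, SD, n = 2), and the one missing from phyB-9 stood at -3.46 ± 1.26 in Col-0 at day 0.

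Replicates of day 4 differed along the far-red response itself. The difference between the 2 Col-0 arrays of day 4 correlated with the mean day difference at r = 0.47 across probes, that between the phyB-9 arrays at r = -0.42 and that between the phyA-211 arrays at r = 0.17, while at day 0 the values lay between -0.23 and -0.07. The SD between replicates was 0.38, 0.31 and 0.36 on the log2 scale in Col-0, phyB-9 and phyA-211 at day 4, and 0.42, 0.41 and 0.45 at day 0, so the day 4 arrays were not noisier as a whole.

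One hypothesis was that the far-red response of phyB-9 is a uniformly smaller copy of that of phyA-211. Then nearly every called difference between their responses would run against the Col-0 response, up to the 5% of false calls allowed. Of the 5009 called differences, 3537 (70.6%) did so among probes called in Col-0, 482 (9.62%) ran with the Col-0 response, with a larger response in phyB-9, and 990 were not called in Col-0. A common scaling may therefore hold for most but not for all of these probes. A first test, a bound on the correlation between the day 4 difference of the mutants and the Col-0 far-red response, gave r = -0.49, too close to that bound to decide, and the share above was taken in its place after that value was seen.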
